A study of Homo sapiens with 6 samples.

How the data were processed

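TIG113 cells, cultured fibroblasts of normal human skin, were transfected with an siRNA against ESRRA, the gene for the orphan nuclear receptor ERRα, or with a negative control siRNA, and total RNA was taken after 48 h, per the labels' protocols. Each of the 6 RNA samples was labelled with Cy3 as cRNA and hybridised to its own 1-colour Agilent array. The groups follow the sample titles: siERRA, 3 arrays, and siNC, 3 arrays. The 6 arrays lay on 1 slide with 1 scan date in the file headers, so neither slide nor scan could be separated into batches. In the slide's layout each siNC array lay beside the siERRA array of the same replicate number. The siNC arrays 1, 2 and 3 lay in columns 1, 3 and 1 of the slide. The siERRA arrays 1, 2 and 3 lay in columns 2, 4 and 2, so the column cannot be separated from the group.

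The deposited scanner files hold spot intensities on a linear scale. Per the file headers, Agilent Feature Extraction subtracted the background and detrended the signal, with no scaling between arrays, and the submitters' processing notes give version 11.0.1.1. The deposited value table of the series also holds intensities on a linear scale. Its columns equalled each array's processed signal averaged over the spots of a probe, for 100% of probes within a relative tolerance of 1e-04, so its scale, centring and direction are those of the scanner files, and its medians ran from 12.4 to 14.4. It was used only as an alternative.

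Each array had 62976 spots and 58201 different non-control probes. Control spots were left out. Values were log2 of the processed signal minus the array's 75th percentile over non-control spots, which lay between 256 and 282 intensity units. Spots with an outlier flag, 88 to 129 per array, were set aside where another spot of the same probe remained, and spots of a probe were averaged. No spot was saturated. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 27201 probes. Between 47.8% and 49.0% of probes were well above background on each array, and the number of arrays limits the precision.

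Genes were named by matching the accession of each probe, without its version, to RefSeq genes of the assembly GRCh38.p14. The files name hg19 as their annotation build, so no coordinates are given. Of the 58201 probes, 31104 (53.4%) matched a gene. The other 27097 stayed unnamed, and those kept were tested as themselves. A gene with several kept probes, as 3972 genes had, was represented by the probe with the highest mean over the 6 arrays. This left 22209 features, made up of 15011 genes and 7198 unnamed probes. Of the genes named in the text, ATG16L1 and CXCL12 had kept probes that differed in sign.

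The comparison was siERRA minus siNC over all 6 arrays, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 22209 features. Files were read with the data.table package, version 1.17.8. An adjusted p below 0.05 counted as a change, and "rose" and "fell" are used only of genes that passed. Log2 fold changes are given with their standard error (SE), and levels as mean ± SD of 3 arrays. Where a probe was not well above background on any array of a group, the change is given as "at least N-fold": the mean of the bright group against the mean, over the dim arrays, of the higher of the probe's own value and the lowest value among the probes well above background on that array. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

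Before the data were examined, 36 gene lists were fixed from textbook knowledge of ERRα, mitochondria, dermal fibroblasts, siRNA transfection and the other cell types of skin. The 35 lists with at least 5 measured members were tested with camera of limma, a test of whether a list's members shift relative to all other features, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 35. In all, 18 lists passed, 5 up and 13 down. None of these calls held when the correlation was estimated for each list, with adjusted p between 0.33 and 0.72 for these 18. That p is given beside each list as "with an estimated correlation". The correlation was estimated without the replicate block described below, so it includes any deviation that same-numbered arrays share. It was not estimated with that block. With fry, which asks whether a list's members move one way on balance without comparing them with other genes, 19 lists passed, not all of them among the 18. Counts described as adjusted over the list alone use Benjamini-Hochberg within the list.

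The genes named were also fixed by a rule before the data were examined. They were ESRRA, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with separated groups, an official symbol and a probe well above background on all 6 arrays, up to 2 genes each way that were not well above background on any array of 1 group, and of each list the 2 members with the smallest adjusted p, or 4 where the list passed. Further genes are named where 5 or fewer members of a list moved one way, or are singled out, and these were chosen after their values were seen. Some genes that these rules take are not reported here. Those chosen after include members of the caspase, FKBP, CFAP, SNORA and TLR families, LEP, PARN, MTREX, SCARNA8, SCARNA10, SCARNA11, SCARNA14, LDHD, ACTA2, COL3A1, ELN, CDKN2B, FASN, HSPA5, HSP90B1, ATF3, IFIH1, RIGI, ISG15, OASL, PDPN, ESR1, CXCL2 and LDHA.

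Replicate numbers come from the sample titles. Whether they pair the samples was checked by the correlation, across features, of the deviations of same-numbered arrays from their group means, which was 0.20, 0.45 and 0.48 for replicates 1, 2 and 3. All lay over 0.1, so the numbers were taken to pair the samples. The pairing also follows the neighbouring positions on the slide. The fit with the replicate number as a block was an alternative.

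The other alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the value table, no filter on dim probes, a probe well above background on all arrays, the mean of a gene's probes, an intensity trend with robust eBayes, Welch's test per gene, and each array left out in turn. Normexp was run on the median spot signal, since the files hold no mean spot signal. A scaling to the 75th percentile over spots detected on all arrays was added after the data were seen. The median log2 fold change over all features was 0.02, and no scaling moved it by over 0.1.

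The fits were tested on simulated data with the means and spreads of the 22209 features of this comparison and a set of features changed by known folds. Features were drawn independently of each other and without pairing. Only 67, 67 and 66 of them were changed 1.5-, 2- and 4-fold, far fewer than changed in the data. The limma fit recovered 37.3% of the features changed 1.5-fold, 77.6% of those changed 2-fold and 90.9% of those changed 4-fold, and called 5 unchanged features. A shift of −0.3 put on the TCA cycle list was called by camera, with the preset correlation and with an estimated one (adjusted p = 0.0069), and with the preset one 0 of 32 other lists were. The simulated lists held no correlation between genes, whereas the estimate for the TCA cycle list in the data was 0.32. These list results therefore do not measure false calls or power for lists in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.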

Results

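The series compared gene expression in TIG113 cells, human skin fibroblasts, 48 h after transfection with siRNA against ESRRA or with a negative control siRNA. ESRRA encodes ERRα, an orphan nuclear receptor known for its control of mitochondrial genes. The 6 samples, 3 per group, were each measured on 1 array of 62976 spots, and 47.8% to 49.0% of the probes on an array lay well above background. The groups are called siERRA and siNC below. Each group received 1 siRNA product, and the products came from different makers, so the product differed between the groups along with its target. The question the design implies is which transcripts differed when ERRα was silenced.

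ESRRA itself was lower on every siERRA array. On the probe with the higher signal, A_23_P1585, the level was 3.79 ± 0.05 (SD, n = 3) in siNC and 0.52 ± 0.27 (SD, n = 3) in siERRA, in log2 units relative to the array's 75th percentile. The siERRA values were 0.53, 0.25 and 0.78 on replicates 1, 2 and 3. The log2 fold change was −3.27 with an SE of 0.14, which left 10.4% of the control signal (limma, adjusted p = 0.00033). The other probe, A_33_P3243544, gave −3.34, or 9.87% of the control signal.

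**Figure D1:**
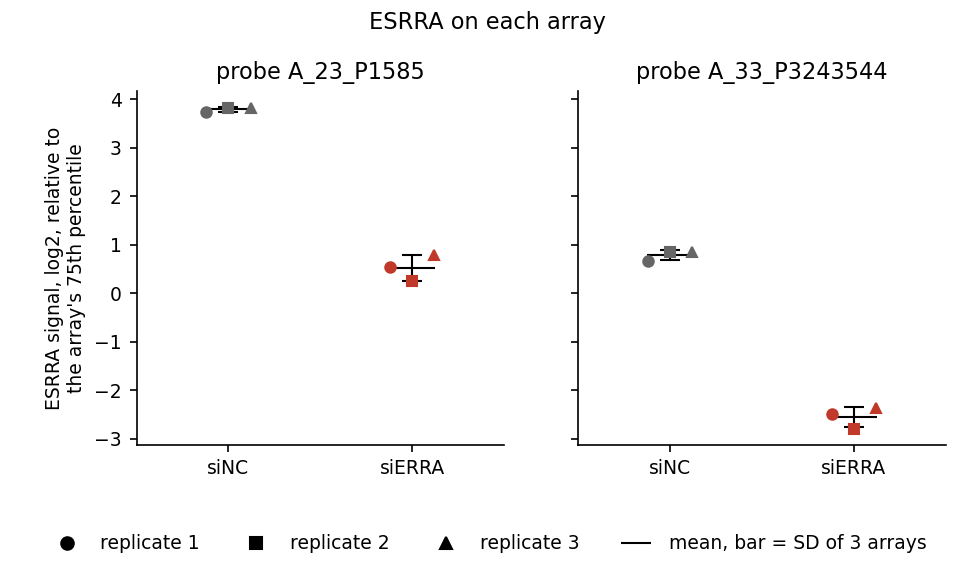
ESRRA signal on each array (log2, relative to the array's 75th percentile) for both ESRRA probes, in siNC (grey) and siERRA (red), with the marker shape giving the replicate and the black bars the mean and SD of 3 arrays. On probe A_23_P1585 the siERRA arrays lie between 0.25 and 0.78, all below the siNC arrays, which lie between 3.74 and 3.82.

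Of 15011 genes tested, 4382 (29.2%) changed, 1930 of them higher and 2452 lower in siERRA. Most changes were small, and 471 genes changed at least 2-fold, 211 higher and 260 lower, or 171 with normexp background correction. The values of the groups did not overlap for 7677 genes (51.1%). For a single gene, random labels would give this in 10% of cases. Genes on the same arrays vary together, so the share over genes can lie far from 10%. It was not measured for other splits of the arrays. Among the 7198 unnamed probes, 872 changed, 432 higher and 440 lower. Among the limma fits, the count of changed genes fell by over 1.5 times without siNC 1 (2237), siNC 2 (2282), siNC 3 (2729) or siERRA 1 (2452), and with the probes dim in both groups included (2271). With median scaling 1224 genes were higher and 2030 lower.

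The 10 genes with the largest rise among those measured on all arrays were MX1, IFI44L, SCARNA13, IFITM1, HERC5, EPSTI1, CMPK2, SCARNA20, AKR1B15 and GPAT3, with log2 fold changes from 2.83 down to 2.09. MX1, IFI44L, IFITM1, HERC5, EPSTI1 and CMPK2 are interferon-induced, SCARNA13 and SCARNA20 are small Cajal body RNAs, a class that guides the modification of spliceosomal RNA, and GPAT3 is an acyltransferase of triglyceride synthesis. SCARNA13 rose from 0.49 ± 0.01 to 3.08 ± 0.13 (SD, n = 3 per group). AKR1B15 is a near-identical copy of AKR1B10, an aldo-keto reductase that rose by about as much (2.08), and the probes may not tell them apart. The 10 with the largest fall were KRT14, KRT16P2, PHF20, CEND1, PLEKHB1, CAND2, SUSD1, REEP2, PLCE1-AS1 and KRT17, from −2.83 to −1.95. KRT14 and KRT17 are keratins and KRT16P2 a keratin pseudogene, whose probes may share signal. PHF20 fell from 2.11 ± 0.04 to −0.10 ± 0.08 and REEP2 from 2.46 ± 0.05 to 0.47 ± 0.10 (SD, n = 3 per group). With normexp background correction the log2 fold changes of 9 of these 20 genes were smaller by over 1.5 times, namely EPSTI1 (1.16), HERC5 (0.92), KRT14 (−1.68), KRT16P2 (−1.42), CEND1 (−1.19), CAND2 (−1.08), PLCE1-AS1 (−0.96), PLEKHB1 (−0.94) and KRT17 (−0.82). Not well above background on any siNC array, OAS1, which makes the activator of RNase L, was at least 8.38-fold higher in siERRA (adjusted p = 0.0042) and the transporter gene SLCO2B1 at least 2.85-fold higher (adjusted p = 0.0031). Not well above background on any siERRA array, KPRP, a gene of keratinised skin, was at least 11.7-fold lower (adjusted p = 0.0018) and HOGA1, a mitochondrial aldolase, at least 2.21-fold lower (adjusted p = 0.00033). These bounds hold for the processed signal, and with normexp the log2 fold changes of OAS1, SLCO2B1, KPRP and HOGA1 were 1.3, 0.70, −1.89 and −0.40.

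**Figure D2:**
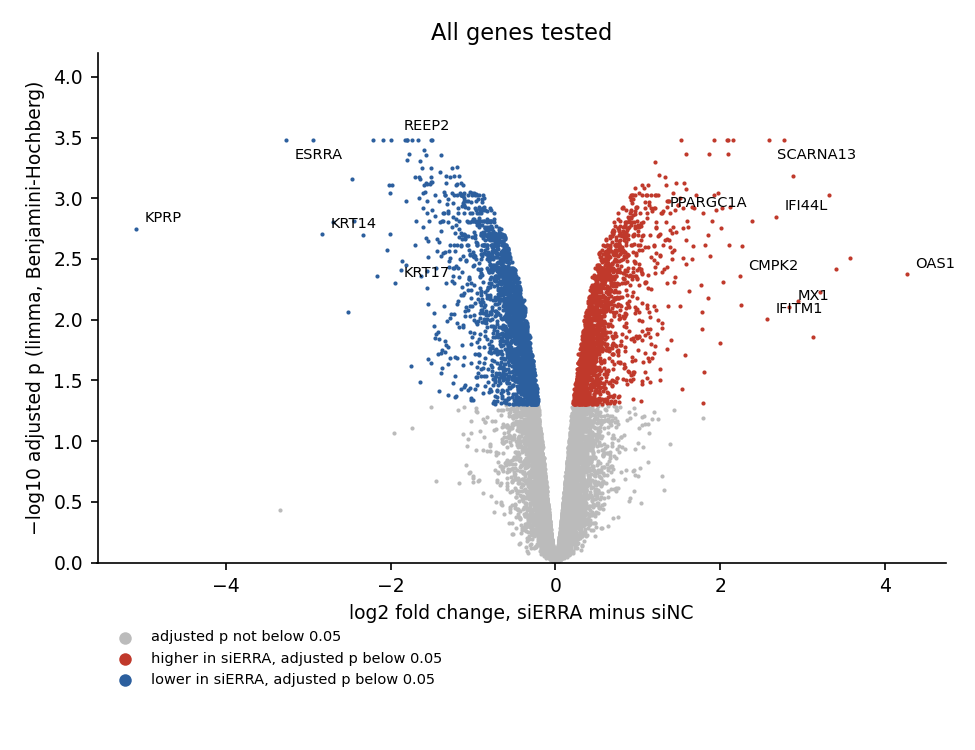
Log2 fold change (siERRA minus siNC, horizontal) against −log10 of the limma adjusted p (vertical) for each gene tested, with the 1930 higher genes in red, the 2452 lower genes in blue and the rest in grey. ESRRA lies at −3.27, and the measured differences of KPRP and OAS1, each dim in 1 group, are plotted although only a bound can be given for their fold.

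Interferon-stimulated genes had the largest median shift of the 35 lists tested, in a comparison where the siRNA product differed between the groups as well. Of 38 measured members, 31 rose with limma, 0 fell and 7 did not pass, and 34 rose when adjusted over the list alone. Their median log2 fold change was 1.26, or 1.21 with dim members at their bounds (camera adjusted p = 2.10e-16, and adjusted p = 0.70 with an estimated correlation). MX1, an antiviral GTPase, rose from 0.87 ± 0.91 to 3.71 ± 0.21 and IFI44L from 0.50 ± 0.42 to 3.18 ± 0.16 (SD, n = 3 per group), and the spread was wider among the siNC arrays. DDX60 rose by 1.39 (SE 0.11) and ISG20, an exonuclease, by 0.78 (SE 0.07). The cytosolic RNA sensors IFIH1 and RIGI rose by 1.1 and 1.16 (RIGI by 0.70 with the mean of its probes), and ISG15 by 1.21. OASL, well above background on 1 siNC array and all siERRA arrays, rose by 3.41 (SE 0.42), or 1.22 with normexp. The chemokine CXCL10 was at least 1.4-fold higher (adjusted p = 0.00033), with no siNC array well above background and a log2 fold change of 0.58 with normexp. The mean level of the 38 genes was −0.07, 0.18 and 0.52 on siNC arrays 1, 2 and 3 and 1.63, 1.71 and 1.43 on siERRA arrays 1, 2 and 3.

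Inflammatory and senescence-associated cytokine genes also shifted up. Of 25 measured, 12 rose, 5 fell and 8 did not pass, and adjusted over the list alone 15 rose and 6 fell. The median was 0.41 (camera adjusted p = 0.015, and adjusted p = 0.70 with an estimated correlation). RELB, an NF-κB subunit, rose by 1.02 (SE 0.06), TNFAIP6, a hyaluronan-binding protein, by 1.19 (SE 0.09) and CXCL2 by 1.62. CCL5 was at least 2.36-fold higher (adjusted p = 0.00093), with no siNC array well above background and a log2 fold change of 0.62 with normexp. The 5 that fell were PTGES, the inducible prostaglandin E synthase, at −1.14 (SE 0.12, −0.44 with normexp), CCL2 at −0.75, GREM1, CXCL5 and CXCL12. GREM1, CXCL5 and CXCL12 lost their calls without siNC 1, siNC 2, siERRA 1 or siERRA 3, GREM1 and CXCL12 also without siNC 3, and CXCL5 and CXCL12 without siERRA 2, with adjusted p up to 0.15. With the mean of its probes the sign of CXCL12 turned, to 0.24, and the call of GREM1 was lost (adjusted p = 0.071). The list's own call was lost when every probe had to be well above background on all arrays (median 0.27, adjusted p = 0.092).

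Genes of the mitochondrial respiratory chain were lower as a group, by small amounts. In none of its lists did the share of members that changed exceed the 29.2% over all genes, of which 1930 rose and 2452 fell. Of 37 measured complex I genes, 0 rose, 10 fell and 27 did not pass (12 fell adjusted over the list alone), with a median of −0.18 (camera adjusted p = 2.23e-05, and adjusted p = 0.70 with an estimated correlation). NDUFA13 stood apart, falling from 5.30 ± 0.05 to 3.78 ± 0.09 (SD, n = 3 per group), a log2 fold change of −1.51 (SE 0.08), while NDUFS6, NDUFS7 and NDUFV1 changed by −0.37, −0.36 and −0.29. Of 24 genes of complexes II to IV and cytochrome c, 0 rose, 6 fell and 18 did not pass (9 fell adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.00063, and adjusted p = 0.70 with an estimated correlation). CYCS, cytochrome c, fell by 0.56, COX6A1 by 0.54, COX8A by 0.48 and UQCRQ by 0.44. ATP synthase had 0 members that rose, 4 that fell and 12 that did not pass of 16 measured (7 fell adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.0035, and adjusted p = 0.70 with an estimated correlation). The 4 were ATP5MC1 (−0.51), ATP5F1A (−0.48), ATP5PD (−0.29) and ATP5MC3 (−0.26). Leaving out siNC 1, siNC 2 or siERRA 1 ended the calls of NDUFS6, NDUFS7, NDUFV1, ATP5F1A, ATP5PD and ATP5MC3, with adjusted p up to 0.14, and siNC 3, siERRA 2 or siERRA 3 left out ended some of them.

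The tricarboxylic acid (TCA) cycle and mitochondrial ribosome lists moved the same way, again with no larger share of changed members than the 29.2% over all genes. For the mitochondrial ribosome the share that fell was also near that over all genes, 2452 of 15011. Of 25 TCA cycle genes, 0 rose, 6 fell and 19 did not pass (8 fell adjusted over the list alone), with a median of −0.21 (camera adjusted p = 0.0002, and adjusted p = 0.70 with an estimated correlation). IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase, fell by 0.74 (SE 0.06), SUCLA2, a subunit of succinyl-CoA ligase, by 0.66 (SE 0.08), DLD by 0.56 (−0.28 with normexp) and PDHA1 by 0.40. Of 42 mitochondrial ribosomal protein genes, 1 rose, 8 fell and 33 did not pass, with the same counts adjusted over the list alone, and the median was −0.17 (camera adjusted p = 0.0019, and adjusted p = 0.71 with an estimated correlation). MRPS9 fell by 0.50 and MRPS12 by 0.47, MRPL1 by 0.40 (−0.27 with normexp) and MRPL12 by 0.37, and the 1 that rose was MRPL10 at 0.29. The calls of MRPL1, MRPL12 and MRPL10 were lost without siNC 2 or siERRA 1, those of MRPL1 and MRPL10 also without siNC 3, those of MRPL12 and MRPL10 without siNC 1, and that of MRPL10 without siERRA 2 or siERRA 3, with adjusted p up to 0.11.

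Among 33 measured genes that textbooks give as ERRα targets, 25 of the 35 listed being in another list too, 2 rose, 10 fell and 21 did not pass, and adjusted over the list alone 4 rose and 11 fell. The median was −0.13 (camera adjusted p = 0.033, and adjusted p = 0.71 with an estimated correlation), and the call was lost without siNC 2 or siERRA 3 (adjusted p = 0.089 and 0.094). SUCLA2, COX8A and CYCS were among those that fell, with SLC25A4, the ADP/ATP carrier (−0.63, SE 0.09), and LDHD, D-lactate dehydrogenase (−1.56, or −0.49 with normexp). The 2 that rose were SPP1, osteopontin (0.74, SE 0.07), and ACADM, medium-chain acyl-CoA dehydrogenase (0.36), whose call was lost without siNC 1, siNC 3 or siERRA 1 (adjusted p up to 0.070). Of 13 measured ERR family members and coregulators, 2 rose, 1 fell and 10 did not pass, the same adjusted over the list alone, and the list did not pass (median 0.13, camera adjusted p = 0.080), but did without siNC 2 (adjusted p = 0.027). PPARGC1A, which encodes the ERRα coactivator PGC-1α, rose by 1.28 (SE 0.10), and NRF1, a regulator of nuclear-encoded mitochondrial genes, by 0.52 (SE 0.13), or 0.75 and 0.32 with normexp. PPRC1 fell by 0.26. The call of NRF1 was lost without any 1 of siNC 1, siNC 2, siNC 3, siERRA 1 or siERRA 3 (adjusted p up to 0.099), and that of PPRC1 without any 1 array (adjusted p up to 0.16) and with the replicate block (adjusted p = 0.056).

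Mitochondrial biogenesis and dynamics genes went both ways. Of 29 measured, 3 rose (PPARGC1A, NRF1 and TFAM, the mitochondrial transcription factor, at 0.55), 3 fell (OPA1, DNM1L and TIMM17A) and 23 did not pass, the same adjusted over the list alone. The list did not pass (camera adjusted p = 0.78), and its median of −0.03 and mean of 0.03 differed in sign. Fatty acid oxidation had 3 genes that rose (CPT1A, CPT1B and ACADM), 7 that fell and 14 that did not pass of 24, the same adjusted over the list alone (median −0.08, camera adjusted p = 0.17). CPT1C fell by 1.13 (SE 0.08). Of 26 glycolysis genes, 2 rose, 7 fell and 17 did not pass, the same adjusted over the list alone (median −0.09, camera adjusted p = 0.14). SLC2A3, a glucose transporter, rose by 1.34 (SE 0.11), with PFKFB3 at 0.34, while ALDOC fell by 1.30 (SE 0.11, −0.85 with normexp) and LDHA by 0.63. Both of these lists passed, with a shift down, when dim probes were not filtered (adjusted p = 0.0035 and 0.0026). The calls of DNM1L, TIMM17A, CPT1B, ACADM and PFKFB3 were lost without siNC 1, and some of them without siNC 2, siNC 3, siERRA 1 or siERRA 2 (adjusted p up to 0.088).

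Genes of lipid synthesis were lower as groups. Of 25 cholesterol synthesis genes, 0 rose, 14 fell and 11 did not pass (15 fell adjusted over the list alone), with a median of −0.32 (camera adjusted p = 2.69e-06, and adjusted p = 0.70 with an estimated correlation). CYP51A1, lanosterol demethylase, fell from 4.72 ± 0.06 to 3.56 ± 0.07 (SD, n = 3 per group), and PMVK, EBP and TM7SF2 fell by 1.01, 0.76 and 0.72 (TM7SF2 at −0.45 with normexp). Of 20 genes of fatty acid and triglyceride synthesis, 2 rose, 9 fell and 9 did not pass, and adjusted over the list alone 2 rose and 11 fell. The median was −0.34 (camera adjusted p = 0.0048, and adjusted p = 0.70 with an estimated correlation). FABP3, a fatty acid binding protein, fell by 1.61 (SE 0.10), GPAM, a mitochondrial glycerol-3-phosphate acyltransferase, by 1.21 (SE 0.07), ACACA, acetyl-CoA carboxylase, by 0.66 and FASN, fatty acid synthase, by 0.81. PLIN2, a lipid droplet coat protein, rose by 0.85 (SE 0.08), and PPARG was the other that rose, by 0.48.

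Genes of DNA replication and mitosis were lower as groups. Of 37 S phase genes, 0 rose, 27 fell and 10 did not pass (30 fell adjusted over the list alone), with a median of −0.52 (camera adjusted p = 1.32e-13, and adjusted p = 0.58 with an estimated correlation). TK1, thymidine kinase, fell by 0.86 (SE 0.08), MCM6, of the replicative helicase, by 0.80 (SE 0.07), PCNA, the polymerase clamp, by 0.64 (SE 0.06) and RFC4 by 0.62 (SE 0.06). Of 39 genes of G2 and mitosis, 1 rose, 26 fell and 12 did not pass, and adjusted over the list alone 1 rose and 29 fell. The median was −0.37 (camera adjusted p = 9.50e-10, and adjusted p = 0.33 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, fell by 0.85 (SE 0.07), the spindle motor KIF11 by 0.78 and PRC1 by 0.57, while CDC25B, a phosphatase that activates cyclin-dependent kinases, was the 1 that rose, by 0.93 (SE 0.07). Among 32 p53 targets and senescence genes, 14 rose, 2 fell and 16 did not pass, with 16 rising and 2 falling when adjusted over the list alone. The median was 0.23 (camera adjusted p = 0.00064, and adjusted p = 0.70 with an estimated correlation). TP53INP1 rose by 1.22 (SE 0.11), the CDK inhibitor gene CDKN1C by 1.13 (SE 0.08), BBC3, a pro-apoptotic BCL2 family member, by 1.04 (SE 0.09), SESN1 by 0.83 and CDKN2B, another CDK inhibitor gene, by 1.19 (0.72 with normexp). LMNB1, lamin B1, and TIGAR were the 2 that fell, by 1.41 and 1.14.

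Of 31 proteoglycan and glycoprotein genes, 1 rose, 11 fell and 19 did not pass, and adjusted over the list alone 2 rose and 15 fell. The median was −0.27, or −0.09 with normexp (camera adjusted p = 0.0097, and adjusted p = 0.71 with an estimated correlation). TNC, tenascin C, fell by 0.99 (SE 0.18), SDC1, syndecan 1, by 0.69 (SE 0.09) and HAPLN3 by 0.44 (SE 0.07), while ASPN, asporin, rose by 1.58 (SE 0.19). Of 38 genes of fibrillar collagens and elastic fibres, 9 rose, 6 fell and 23 did not pass, and adjusted over the list alone 10 rose and 6 fell (median 0.02, camera adjusted p = 0.71). COL5A1 rose by 0.79 (SE 0.09, 0.44 with the mean of its probes), COL1A1 by 0.50 (SE 0.06), COL3A1 by 0.55 and ELN, elastin, by 0.78. COL5A3, well above background on all siNC arrays and 1 siERRA array, fell by 2.48 (SE 0.14), or −0.87 with normexp. Of 26 matrix proteases and inhibitors, 6 rose, 3 fell and 17 did not pass, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.15). ADAM12 rose by 1.51 (SE 0.10, 0.90 with the mean of its probes), and SERPINE2, ADAMTS5 and ADAMTS4 fell by 0.66, 0.79 and 0.90.

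Several contractile genes fell. Of 27 genes of the TGF-β response and myofibroblasts, 4 rose, 7 fell and 16 did not pass, and adjusted over the list alone 5 rose and 9 fell. The list did not pass (median −0.05, camera adjusted p = 0.20), but did without a filter on dim probes (adjusted p = 0.0084). TAGLN, an actin-binding protein of smooth muscle, fell from 5.73 ± 0.02 to 4.51 ± 0.06 (SD, n = 3 per group), CNN1, calponin, by 1.28 (SE 0.13), ACTA2, smooth muscle actin, by 0.78 and IL11 by 0.96 (SE 0.08, −0.61 with normexp). The 4 that rose were TGFB2 (1.91, or 0.73 with normexp), ID1, ID3 and TGFBR2. Of 10 measured pericyte and smooth muscle markers, 0 rose, 6 fell and 4 did not pass (1 rose and 6 fell adjusted over the list alone), with a median of −0.46, or −0.14 over the members measured with no filter on dim probes (camera adjusted p = 0.0063, and adjusted p = 0.70 with an estimated correlation). LMOD1 fell by 1.44 (SE 0.15, −0.78 with normexp), MCAM by 1.09 (SE 0.08) and KCNJ8 by 0.55 (SE 0.09). Growth factors of fibroblasts, with 4 that rose, 7 that fell and 16 that did not pass of 27, did not pass as a list (5 rose and 7 fell adjusted over the list alone, median −0.09, camera adjusted p = 0.34). FGF2 fell by 1.32 (SE 0.09) and FGF5 by 0.81 (SE 0.09), and GDF15, PDGFRA, PDGFA and IGF1 rose. The calls of PDGFA and IGF1 were lost without siNC 1, siNC 2, siNC 3 or siERRA 1, and that of IGF1 also without siERRA 2 (adjusted p up to 0.099) and with normexp (adjusted p = 0.083).

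**Figure D3:**
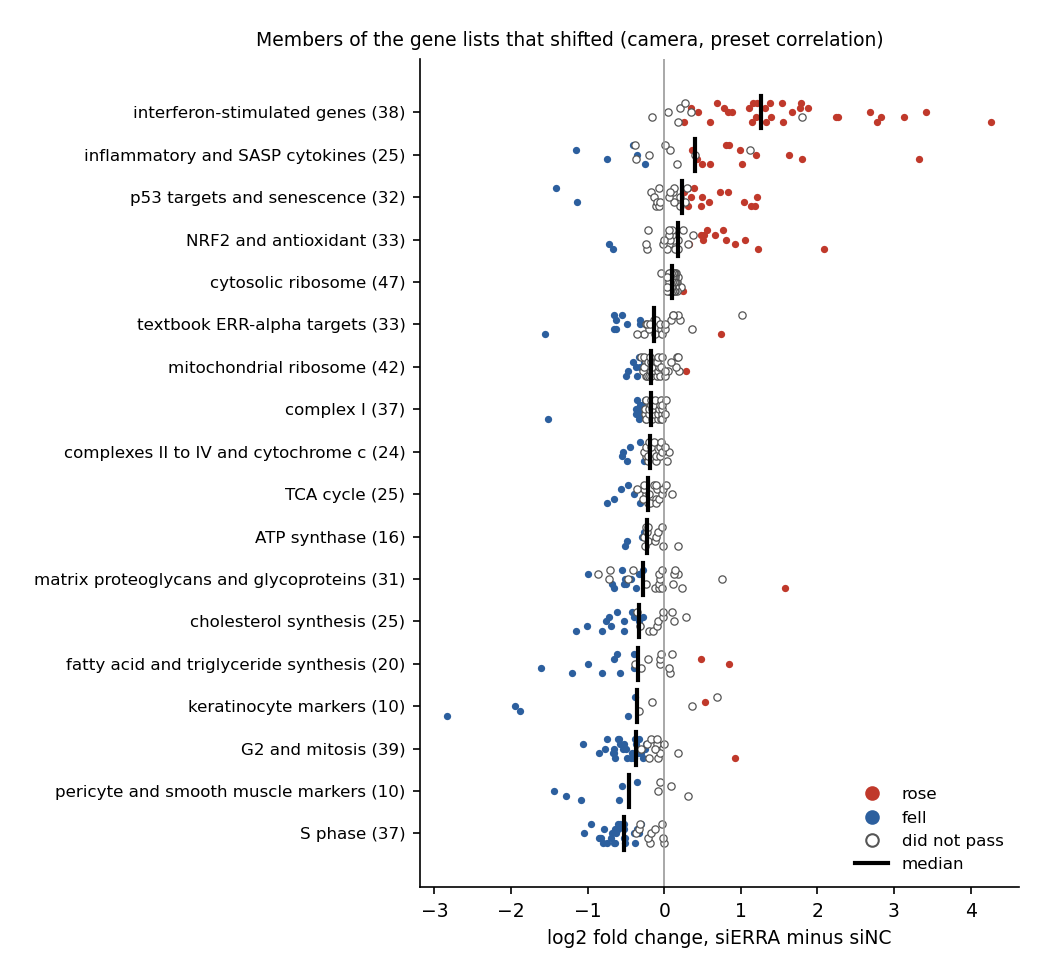
Log2 fold change (siERRA minus siNC) of each measured member of the 18 lists that passed camera with the preset correlation, with the number measured in brackets, members that rose in red, members that fell in blue, members that did not pass as open circles and the list median as a black line. The medians run from −0.52 for S phase to 1.26 for interferon-stimulated genes, and none of the 18 calls held with an estimated correlation.

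Of 33 NRF2 and antioxidant genes, 12 rose, 2 fell and 19 did not pass, and adjusted over the list alone 12 rose and 5 fell. The median was 0.18 (camera adjusted p = 0.0012, and adjusted p = 0.70 with an estimated correlation). AKR1B10 rose by 2.08 (SE 0.08), SLC7A11, the cystine transporter, by 0.92 (SE 0.10), SOD2 by 0.81 and GSR, glutathione reductase, by 0.52, while ME1 and SRXN1 fell. Of 43 genes of ATF4 and the unfolded protein response, 11 rose, 13 fell and 19 did not pass, and adjusted over the list alone 14 rose and 13 fell (median −0.13, camera adjusted p = 0.62). SLC3A2, the partner of SLC7A11, rose by 0.88 (SE 0.07) and ATF3 by 1.44 (0.65 with the mean of its probes), whereas the endoplasmic reticulum genes CRELD2, HSP90B1 and HSPA5 fell by 0.97, 0.70 and 0.48. Of 20 heat shock genes, 3 rose (HSPA8, HSPA1A and HSPA1B), 2 fell (CHORDC1 at −0.56 and HSP90AA1 at −0.37) and 15 did not pass (4 rose and 2 fell adjusted over the list alone, median −0.11, camera adjusted p = 0.45). Of 46 autophagy and lysosome genes, 9 rose, 2 fell and 35 did not pass, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.080). ULK1, an autophagy kinase, rose by 0.52 (SE 0.06), and CTSZ, cathepsin Z (−1.27, SE 0.21), and ATG16L1 were the 2 that fell. That list passed with quantile normalization and without siNC 2 or siERRA 3 (adjusted p = 0.047 to 0.050). The calls of SRXN1, HSPA8, HSPA1A, HSPA1B, HSP90AA1 and ATG16L1 were lost without siERRA 1, all but that of SRXN1 without siNC 1, all but that of HSPA8 without siNC 2, all but that of HSP90AA1 without siNC 3, and those of HSPA1A, HSPA1B and ATG16L1 without siERRA 2 (adjusted p up to 0.15), and that of ATG16L1 with the mean of its probes (adjusted p = 0.69).

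Of 24 hypoxia response genes, 5 rose (KDM3A, DDIT4, CITED2, PFKFB3 and NDRG1), 6 fell and 13 did not pass, with 5 rising and 7 falling when adjusted over the list alone (median −0.05, camera adjusted p = 0.71). KDM3A, a histone demethylase, rose by 0.72 (SE 0.08), and ALDOC fell by 1.30, or 0.48 and −0.85 with normexp. Of 17 circadian clock genes, 4 rose (BMAL1, CRY2, NFIL3 and RORA), 2 fell (BHLHE40 and TEF) and 11 did not pass, and adjusted over the list alone 5 rose and 3 fell (median 0.17, camera adjusted p = 0.25). BMAL1 rose by 0.61 (SE 0.07) and BHLHE40 fell by 0.63 (SE 0.07). Of 28 oestrogen and steroid hormone genes, 7 rose, 2 fell and 19 did not pass, the same adjusted over the list alone (median 0.18, camera adjusted p = 0.11). PPARA rose by 0.78 (SE 0.08) and ESR1, the oestrogen receptor, by 1.05, or 0.43 and 0.59 with the mean of their probes and 0.50 for ESR1 with normexp, and GPER1 (−0.77, SE 0.08) and HSD17B12 fell. Cytosolic ribosomal protein genes moved little, with 1 that rose, 0 that fell and 46 that did not pass of 47, and 0 either way adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.00063, and adjusted p = 0.72 with an estimated correlation), and the call was lost with quantile normalization (median 0.04, adjusted p = 0.15). RPS7 rose by 0.25 (SE 0.06), and RPL28 (0.22, but 0.52 and past the threshold with the mean of its probes), RPL4 (0.17) and RPL18 (0.17) did not pass. The calls of RPS7, PFKFB3, NDRG1 and RORA were lost without siNC 1, siNC 2, siNC 3 or siERRA 1, and all but that of RORA without siERRA 2, that of NDRG1 also without siERRA 3 (adjusted p up to 0.13).

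Markers of the other cell types of skin went in different directions. Of 10 measured keratinocyte markers, 1 rose, 5 fell and 4 did not pass, and adjusted over the list alone 2 rose and 6 fell. The median was −0.36, or −0.10 over the members measured with no filter on dim probes (camera adjusted p = 0.044, and adjusted p = 0.70 with an estimated correlation). The call was lost with the replicate block (adjusted p = 0.057) and without siNC 1, siNC 3, siERRA 2 or siERRA 3 (adjusted p = 0.052 to 0.065). KRT14 fell from −0.11 ± 0.25 to −2.94 ± 0.49 and FLG, filaggrin, from −0.22 ± 0.36 to −2.10 ± 0.32 (SD, n = 3 per group), and KRT17, KRT10 and SBSN also fell, while LAMB3 rose by 0.53 (SE 0.10). The calls of KRT10 and SBSN were lost without siNC 1, siNC 2, siNC 3 or siERRA 1, and that of LAMB3 without siERRA 1 (adjusted p up to 0.10). Of 7 endothelial markers, 2 rose (EMCN at 0.94, SE 0.11, and EGFL7 at 0.26), 0 fell and 5 did not pass, the same adjusted over the list alone (median 0.26, camera adjusted p = 0.080). This list passed with the replicate block (adjusted p = 0.047), without siNC 1 (adjusted p = 0.032) and without a filter on dim probes (median 0.14, adjusted p = 0.046), and the call of EGFL7 was lost without any 1 array (adjusted p up to 0.16). Of 11 leukocyte markers, 2 rose (CPA3 at 1.97, SE 0.12, and CD163 at 1.05, or 0.56 with normexp), 2 fell (CD14 at −0.63, SE 0.07, and CSF1R) and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.78). The median was −0.09, camera's direction was down and the mean was 0.12. The call of CSF1R was lost without siNC 1, siNC 2, siNC 3 or siERRA 1 (adjusted p up to 0.14) and with normexp (adjusted p = 0.12). Only 4 melanocyte markers were measured, too few for the test. KIT fell by 1.26 (SE 0.08), 0 rose and 3 did not pass, among them MITF (0.24, SE 0.08), and adjusted over the list alone 1 rose and 1 fell. Of 23 dermal fibroblast markers, 4 rose (COL1A1, COL3A1, PDGFRA and LRIG1), 7 fell and 12 did not pass, and adjusted over the list alone 5 rose and 7 fell (camera adjusted p = 0.78). The median was 0.10 and the mean −0.01. THY1, which encodes CD90, fell by 0.71 (SE 0.07), and PDPN, podoplanin, by 0.95 (−0.40 with normexp). The call of LRIG1 was lost without siNC 2 or siERRA 1 (adjusted p up to 0.068).

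**Figure D4:**
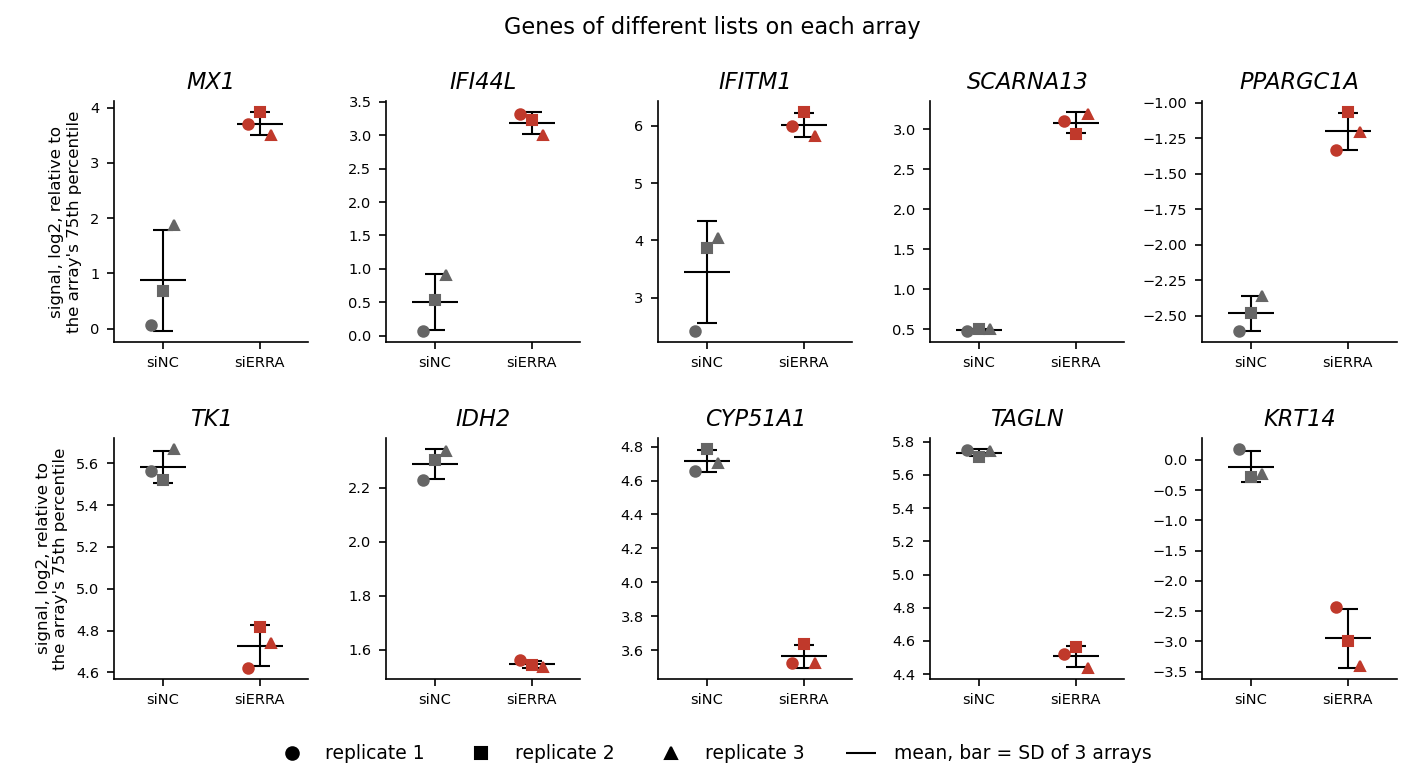
Signal of 10 genes on each array (log2, relative to the array's 75th percentile, with a separate vertical scale in each panel), in siNC (grey) and siERRA (red), with the marker shape giving the replicate and the black bars the mean and SD of 3 arrays. The values of the groups do not overlap for any of the 10, and MX1 spreads more among the siNC arrays (SD 0.91) than among the siERRA arrays (SD 0.21).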

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

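The percentile over detected spots was chosen after the data were seen, and the other settings before. ESRRA fell past the threshold under every alternative run. The 4382 genes changed became 2271 with no filter on dim probes (987 higher, 1284 lower) and 1645 with Welch's test (745 higher, 900 lower, 5612 at an unadjusted p under 0.05). In the self-test Welch's test recovered 25.4% of features changed 2-fold, and limma 77.6%. The replicate block recovered 26.9% there, although it called more genes in the data than limma without it. The simulation held no pairing and few changed features, so these shares need not hold for the data. Among the calls lost with Welch's test were those of MX1, OASL, IFIH1, IFITM1, EPSTI1, HERC5, CMPK2, OAS1, SLCO2B1, KRT17, PLEKHB1 and SUSD1, with adjusted p from 0.051 to 0.13, and 9 interferon-stimulated genes rose in place of 31. Without a filter 22439 genes were tested in place of 15011. Median scaling gave 1224 higher and 2030 lower genes, and the cause was not tested. Genes changed at least 2-fold, 471, became 171 with normexp and 258 with Welch's test. Normexp took another spot signal, background method and offset together, and which of them lowered the count was not tested. It moved the log2 fold change of 45 of the named genes that passed by over 1.5 times, and the mean of probes that of 9. With 1 array left out the ranges were 2237 to 3663 genes changed, 1005 to 1692 higher and 1232 to 2172 lower. The number of arrays is smaller there, and siNC 1, siNC 2, siNC 3 and siERRA 1 each took the count below 4382 by over 1.5 times. The share of higher genes among those changed stayed within 10 points of 44.0% under every alternative. With the replicate block as the pairing, 5052 genes changed, 4172 of them shared with the 4382 and 0 in the opposite direction. The block gave 18 lists, 17 of them shared. It ended the calls of the keratinocyte list and of PPRC1, brought the endothelial list past the threshold, and changed no other call among the lists and named genes. The 18 lists became 0 with the correlation estimated per list, which widens the variance of a list's mean. That correlation was estimated without the replicate block. With fry 19 lists passed, but not all of them were among the 18. The textbook ERRα target, mitochondrial ribosome, proteoglycan and glycoprotein, and cytosolic ribosome lists did not pass fry (fry adjusted p = 0.061 for each). Lists called by fry and not by camera were ERR family and coregulators, fatty acid oxidation, TGF-β response and myofibroblast, circadian clock, and endothelial markers. Of 214 named genes that passed, 170 passed without any 1 array as well, 44 lost the call without at least 1 array, 92 lost it with Welch's test, 40 with no filter and 22 with median scaling. CXCL12, whose probes differ in sign, was 0.24 with the mean of its probes. For other named genes and lists no call changed direction. The slide as a block was not run, since all arrays lay on 1 slide. Signal over background limits the fold of genes dim in a group to a bound.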

Other observations

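The patterns weighed below were noticed in the data, the tests of gene families by symbol, of leukocyte markers, of keratinocyte RNA and of the siRNA products were chosen after the results they measure were seen, and so were the margin of 1 SE by which a median had to pass its bound and the use of the keratinocyte list's median without each array, while the other tests were chosen before the values they measure were seen. Genes that share the root of their symbol were tested as families, 167 with at least 10 members, and 13 passed camera with the preset correlation, none with an estimated correlation (adjusted p = 0.89 for each of the 13). Of 12 genes with the root CASP, most of them caspases, 6 rose and 0 fell, with a median log2 fold change of 0.40 (adjusted p = 0.0098). CASP1, CASP4 and CASP5, of inflammasome signalling, rose by 1.00, 0.79 and 0.82, and the pseudogene CASP4LP by 0.70 (0.32 with normexp). Of 13 FKBP genes, which encode prolyl isomerases, 8 fell and 0 rose, with a median of −0.27 (adjusted p = 0.013). FKBP10 and FKBP14, which act on collagen folding in the endoplasmic reticulum, fell by 0.45 and 0.38, and FKBP3 by 0.58. Of 24 CFAP genes, named for cilia and flagella, 9 fell and 0 rose, with a median of −0.19 (adjusted p = 0.036), and CFAP263 and CFAP119 fell by 1.11 and 0.73 (−0.41 and −0.30 with normexp, and CFAP119 −1.46 with the mean of its probes). The other families were SCARNA, SNORA, SNORD, MIR, ATXN, RPL and RPS, with a shift up, and MCM, MRPL and MRPS, with a shift down. The median of each of the 13 kept its direction under normexp, quantile, median and detected-spot scaling, but some were smaller by over 1.5 times. With normexp these were CASP (0.24), SNORA (0.21), SNORD (0.12), MCM (−0.32) and CFAP (−0.06), with quantile normalization RPL (0.05, from 0.11) and RPS (0.01, from 0.09), and with median scaling RPS (0.06). The calls of FKBP10 and FKBP14 were lost without siNC 1, siNC 2, siNC 3 or siERRA 1, that of FKBP10 also without siERRA 3, and that of CASP4LP without siNC 1, siNC 2 or siNC 3 (adjusted p up to 0.11).

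Among single genes chosen after their values were seen, TLR3, already counted in the interferon-stimulated list, rose by 0.89 and TLR4 by 0.76. TLR2, not well above background on any siNC array, was at least 1.36-fold higher (limma adjusted p = 0.0018, log2 fold change 0.29 with normexp). TLR5 (0.08) did not pass. LEP, leptin, not well above background on any siERRA array, was at least 1.88-fold lower (adjusted p = 0.0087, log2 fold change −0.39 with normexp). Among unnamed probes measured on all arrays, A_32_P76627 and A_33_P3239195 fell by 2.50 and 1.59, and A_21_P0007586 and A_22_P00015676 rose by 1.72 and 1.5.

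The real grouping gave 4382 changed genes, and the highest of the other 9 splits of the 6 arrays into 3 and 3 gave 0 with limma. Welch's test gave 1645 and 0, and at an unadjusted p under 0.05 the real grouping gave 6514 genes and the other splits 79 to 772. The 3 others that, like the real one, part every pair of same-numbered arrays gave 79 to 90, and the 6 that keep a pair together gave 217 to 772. Only 1 of the 10 splits, the real one, gave as many, and with 10 splits the share cannot fall below 0.1. All of the 9 other splits mix siERRA with siNC arrays.

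Interferon-stimulated genes were higher in siERRA. No 1 siERRA array carries this, since without 1 siERRA array at least 65.8% of the measured members still rose. Probes near background do not account for it either, as the members well above background on all 6 arrays had a median log2 fold change of 1.18 (bootstrap SE 0.17). The SE of a median, here and below, comes from resampling genes as if independent. It does not measure the spread between arrays. Leukocytes in the siERRA cultures stay open by the 11 leukocyte markers, which went both ways, with a median of −0.0906 (SE 0.13). CPA3 and CD163 were higher and CD14 and CSF1R lower. All 6 arrays were of 1 cultured fibroblast line, so leukocytes would have to come from outside it. The siRNA product stays open too, because the series holds 1 product against ESRRA and a control of another maker, so a response to the RNA introduced cannot be told apart from an effect of the loss of ERRα, which is the biological candidate explanation and was not tested apart from it.

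Small Cajal body RNAs were higher in siERRA, 14 of 17 measured with 0 lower and a median log2 fold change of 1.02. SCARNA10 and SCARNA8 rose by 1.42 and 2.00, the latter with its call lost without siNC 2 or siERRA 1 (adjusted p up to 0.058), SCARNA11, well above background on 2 siNC arrays, by 3.22, and SCARNA14, on none, at least 7.44-fold (adjusted p = 0.0070), with log2 fold changes of 0.84, 1.64 and 1.16 for SCARNA8, SCARNA11 and SCARNA14 with normexp. The 17 measured genes that contain them, found by position without regard to strand, had a median of −0.14 (bootstrap SE 0.14), with 1 higher and 6 lower. No measured containing gene was found for SCARNA2, while SCARNA16 lay in both SNHG20 (0.50, the 1 higher) and SEC14L1 (0.12). Among the 17 genes are those that contain SCARNA3, SCARNA5 and SCARNA9L, small RNAs that did not pass. The RNA of the containing genes was thus not higher as a set. The arrays measured RNA levels and not transcription, so higher transcription of these genes stays open. More labelled RNA without a poly(A) tail could raise all such RNAs. The 216 others had a median of 0.21 (bootstrap SE over genes 0.02), with 37 higher, among them SNORA48 (1.71) and SNORA63 (1.36), and 0 lower. That median is under the bound of 0.25 set beforehand, although its spread between arrays was not measured. It argues against more labelled RNA as the whole cause of a rise of 1.02. The SNORA among the 216, with 23 of the 37, lay above that bound at 0.32 (SNORD at 0.19), so a part is not excluded. Less of the enzymes that trim their 3' ends stays open, since the lowest of 4 measured, PARN, was at −0.45 (SE 0.09, adjusted p = 0.016) and MTREX at −0.29 (adjusted p = 0.039), calls lost without siNC 1, siNC 2 or siERRA 1, and for MTREX also without siNC 3 or siERRA 3 (adjusted p up to 0.14), and so does the siRNA product.

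Some genes of keratinocyte type were lower in siERRA. Of 10 measured markers 5 fell, with KRT14, KRT17 and FLG the clearest, 1 rose and 4 did not pass. That 1 array carries the fall is argued against, because the median of the list's measured members stayed between −0.40 and −0.33 whichever array was left out. KRT14, KRT17 and FLG also still fell each time, but they were picked because they show the fall, so this decides little. The list's call was lost without siNC 1, siNC 3, siERRA 2 or siERRA 3 (camera adjusted p = 0.052 to 0.065). It was also lost with the replicate block (camera adjusted p = 0.057) and with an estimated correlation (camera adjusted p = 0.70). Keratinocyte RNA in the siNC arrays might give such a fall, but it would bring the other markers too. All 24 listed were on the array and 10 were measured. None of the rest was well above background on all 3 siNC arrays, where such RNA would have to be. They were not part of the test. Of the 7 besides KRT14, KRT17 and FLG, 2 fell, or 28.6%, with an exact binomial upper limit of 71.0%. With so few markers, keratinocyte RNA and an effect of ERRα loss or of the siRNA product cannot be told apart.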
